A study of Homo sapiens with 8 samples.

How the data were processed

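ChIP-seq with an antibody against the FLAG tag was done in MCF7 cells whose endogenous ERα had been replaced by FLAG-tagged WT or RBDmut ERα. Each group had 2 ChIP libraries and 2 input libraries. Libraries were amplified with 18 PCR cycles, size-selected at 200 to 300 bp and sequenced from 1 end to 50 bases on an Illumina HiSeq instrument, per the labels' protocols. The 4 ChIP libraries had a peak list each. No file of the 4 input libraries, no reads and no signal tracks were used here. Groups and replicate numbers came from the sample titles.

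Reads were aligned to GRCh37 (hg19) with Bowtie2, per the submitters' processing notes; the aligner's version is not given in the sources used here. Peaks were called with MACS2 version 2.2.6, separately for each ChIP library against the input library of the same number and not on pooled libraries, per the file headers. The headers give a q-value cutoff of 0.05, at most 1 tag per position and strand, an effective genome size of 2700000000 bp, a band width of 300 bp, a model fold range of 5 to 50, a local background from 1000 and 10000 bp around each peak and no broad-peak calling. The larger of the ChIP and input libraries was scaled to the smaller, per the file headers. The deposited pileup signal is the number of extended tags over the summit after that scaling. The deposited −log10 p-value and −log10 q-value are the peak caller's, with q adjusted within the library. The deposited fold ratio is the pileup at the summit over the local background. The deposited peak length is in base pairs, and positions are counted from 1.

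Keeping 1 tag per position lowers the height of very strong peaks. Scaling within each library leaves pileup, fold and q on a scale of their own in each list, so peaks were compared between lists by position, and numbers of peaks past a fixed fold or q depend on that scale. Ranks were made within each list by −log10 q and then fold, as percentiles with 100 the strongest. Tag numbers after filtering, taken from the headers, were 31492882 and 36834432 for WT replicates 1 and 2 and 33510626 and 33220748 for RBDmut replicates 1 and 2. Those of the matching inputs were 30895348, 40577089, 38203632 and 35561957. A deeper library or input lets weaker peaks pass the threshold, and a list shows presence above a threshold, not the amount bound.

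Overlap was at least 1 bp. The share of peaks in 1 list that overlapped a peak in another was given with its Wilson 95% interval. For a pair, the overlapping peaks of both lists were divided by all peaks of both lists, so a longer list weighs more. The overlap by chance was measured after moving every peak of a list by 1 Mb. Peaks of all lists were merged into regions with no gap allowed (bedtools 2.31.1), and a library held a region if it had a peak in it. Group means were compared by exact permutation of the library labels, two-sided. Numbers of regions were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The correlation across chromosomes used 100000 permutations. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. The overlap and merging steps were tested on 20000 simulated regions with known membership, of which 100% were recovered in every class. Simulated regions lay apart and had a peak in every list of their class. The test checks the steps only, not the loss of peaks near the threshold.

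Local background at a peak was computed as (pileup + 1) / fold − 1, since MACS2 adds 1 to both terms of its ratio. It is the highest of several input-based levels, including a genome-wide one that sets a floor, so it understates differences where the input is low. It was divided by the median over shared regions of the same list and summarised per chromosome and per bin of 10 Mb with at least 8 shared regions, which left 270 bins.

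The regions named in the report followed a rule fixed before the data were examined: the 10 shared regions with the best mean percentile over the 4 lists, the 10 RBDmut-only regions with the best mean over the RBDmut lists and the 10 WT-only regions with the best mean over the WT lists. The mitochondrial chromosome and unplaced contigs were left out. The rule also asked for the nearest gene. The gene table used here is on GRCh38 and the peaks are on GRCh37, so no gene names were attached to peaks. For the same reason, 3 planned results were not run: the genomic annotation of summits, the share of peaks with an estrogen response element or other motif, and the test of estrogen-response and other gene lists.

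Alternatives covered stricter q-value and fold thresholds, 50% reciprocal overlap, summits within 100 bp, lists of equal length, ranking by fold, leaving out each library and pairing libraries by replicate number. The chromosome X cluster, the bins, the local background and its correlation with peak shares, the summit distances, the neighbouring regions and the shares by decile were added after the peak lists had been seen.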

Results

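The data were genome-wide maps of where estrogen receptor α (ERα) sat on chromatin in MCF7 cells, a human breast cancer line that expresses ERα and depends on it for growth. ERα is a nuclear receptor that binds DNA and regulates transcription in response to estrogen. The study is known to treat it as an RNA-binding protein as well. RBDmut is read here, from that knowledge, as a form with changes in the RNA-binding domain, since the labels do not spell the name out. The receptor's own copy in the cells had been replaced, by the series' description in equal amount, by either the wild-type (WT) or the RBDmut protein, each carrying a FLAG peptide tag. Chromatin was immunoprecipitated with an antibody against FLAG and sequenced (ChIP-seq), so both forms were pulled down through the same tag. Each group had 2 ChIP libraries, each with an input library made without immunoprecipitation. The 4 deposited peak lists, 1 per ChIP library, are what was analysed here. After removal of repeated tags the ChIP libraries held 31492882 and 36834432 tags in WT replicates 1 and 2 and 33510626 and 33220748 in RBDmut replicates 1 and 2. The labels do not say whether replicates came from separate cultures, so the spread between them may be technical. With 2 libraries against 2, an exact permutation test has 3 splits and cannot give a p-value below 0.333. Fold enrichment, q-value and the percentile ranks made from them are the authors' peak-caller values and were used to describe, rank and filter the peaks of each list on its own scale. All positions are in GRCh37.

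The first comparison asked whether the RBDmut form differed from WT in how many places it occupied. The RBDmut lists were longer than the WT lists. WT replicates 1 and 2 had 9234 and 11987 peaks, and RBDmut replicates 1 and 2 had 18571 and 18299. The group means were 10610.5 ± 1946.66 (SD, n = 2) in WT and 18435 ± 192.333 (SD, n = 2) in RBDmut, a ratio of 1.74. Both RBDmut lists lay above both WT lists, and the difference of 7824.5 peaks was larger than the spread between replicates (exact permutation test, two-sided, p = 0.333, the smallest this design allows). Peaks covered 3706 ± 696 kb of the genome in WT and 6602 ± 63.4 kb in RBDmut (SD, n = 2). Filtering each list at 10-fold enrichment over its own input left 1638.5 ± 38.9 WT peaks and 3421 ± 11.3 RBDmut peaks (SD, n = 2). At 20-fold or more the numbers were 350.5 ± 6.36 and 739 ± 36.8 (SD, n = 2). The same fold need not mean the same binding in different lists, so these numbers depend on each list's scale. The depth of the ChIP libraries did not follow the lists: the mean number of filtered tags in RBDmut was 0.977 times that in WT, and the groups overlapped. Peak width was close to equal, with medians of 309 bp in each WT list and 310 and 311 bp in the RBDmut lists.

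The fragment length that the peak caller estimated was 199 and 197 bp in the WT libraries and 189 and 190 bp in the RBDmut libraries. The labels give no preparation date, so a batch of library preparation and the ERα form cannot be told apart in any comparison here.

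The second comparison asked whether the WT and RBDmut proteins sat at different places, beyond what replicates of the same form differed by. Most WT peaks were also present in RBDmut cells, and more RBDmut peaks lacked a WT counterpart. Of the peaks of WT replicate 1, 80.3% overlapped a peak of RBDmut replicate 1 by at least 1 bp (Wilson 95% interval 79.4 to 81.1%), and 85.7% overlapped a peak of the other WT list (84.9 to 86.4%). WT replicate 2 went the other way: 74.4 and 74.5% of its peaks overlapped the RBDmut lists, and 65.9% overlapped the shorter list of WT replicate 1 (65.1 to 66.8%). In the other direction, 39.8% of the peaks of RBDmut replicate 1 overlapped a peak of WT replicate 1 and 47.9% a peak of WT replicate 2, against 78.1% for the other RBDmut list. After a list was shifted along the chromosomes by 1 Mb, overlap with any other list fell to between 0.249 and 0.651% of peaks. The intervals cover counting error over the peaks of a list only, since peaks of 1 library are not replicates.

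For each pair, the peaks of both lists were then pooled, and the share that overlapped the other list was taken. This share was 74.5% for the WT pair, 78.7% for the RBDmut pair and 56.0 ± 2.95% for the WT and RBDmut pairs (SD over 4 pairs, range 53.2 to 58.8%). Pairs of the same form overlapped by 20.6 percentage points more than pairs of different forms. Each pair of the same form lay above every pair of different forms, which makes the exact permutation p over 3 splits 0.333, the smallest possible. Because a long list overlaps a short one only in part, each list was also limited to its 9234 strongest peaks by q-value, the length of the shortest list. The overlap was then 77.5% for the WT pair, 82.1% for the RBDmut pair and 62.2 ± 0.228% for the 4 pairs of different forms (SD, range 61.9 to 62.4%). The difference was 17.6 points, and each pair of the same form again lay above every pair of different forms.

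Merging the peaks of all lists gave 25052 regions, of which 6246 held a peak in all 4 libraries and are called shared. A further 5521 regions had a peak in both RBDmut libraries and in neither WT library (RBDmut-only), and 974 had a peak in both WT libraries and in neither RBDmut library (WT-only). Of the 7843 regions found in both WT lists, 79.6% were in both RBDmut lists (Wilson 95% interval 78.7 to 80.5%), and 12.4% were in neither (11.7 to 13.2%). Of the 14391 regions found in both RBDmut lists, 43.4% were in both WT lists and 38.4% were in neither (37.6 to 39.2%). Group-only regions of both kinds added up to 6495, against 439 and 426 for the other splits of the libraries. A total of 8199 regions, or 32.7%, appeared in 1 list only.

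The balance between the group-only classes depended on list length. With every list limited to its 9234 strongest peaks, 1750 regions were RBDmut-only, 1812 were WT-only and 4617 were shared. Here a group-only region lacked a peak among the strongest of the other group, and could have a weaker one. The full lists had 974 WT-only regions, so many of the 1812 had an RBDmut peak below the cut. The counts also depended on single libraries: without WT replicate 1 there were 2403 WT-only regions, and without RBDmut replicate 1 or 2 there were 8633 or 8874 RBDmut-only regions.

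**Figure D1:**
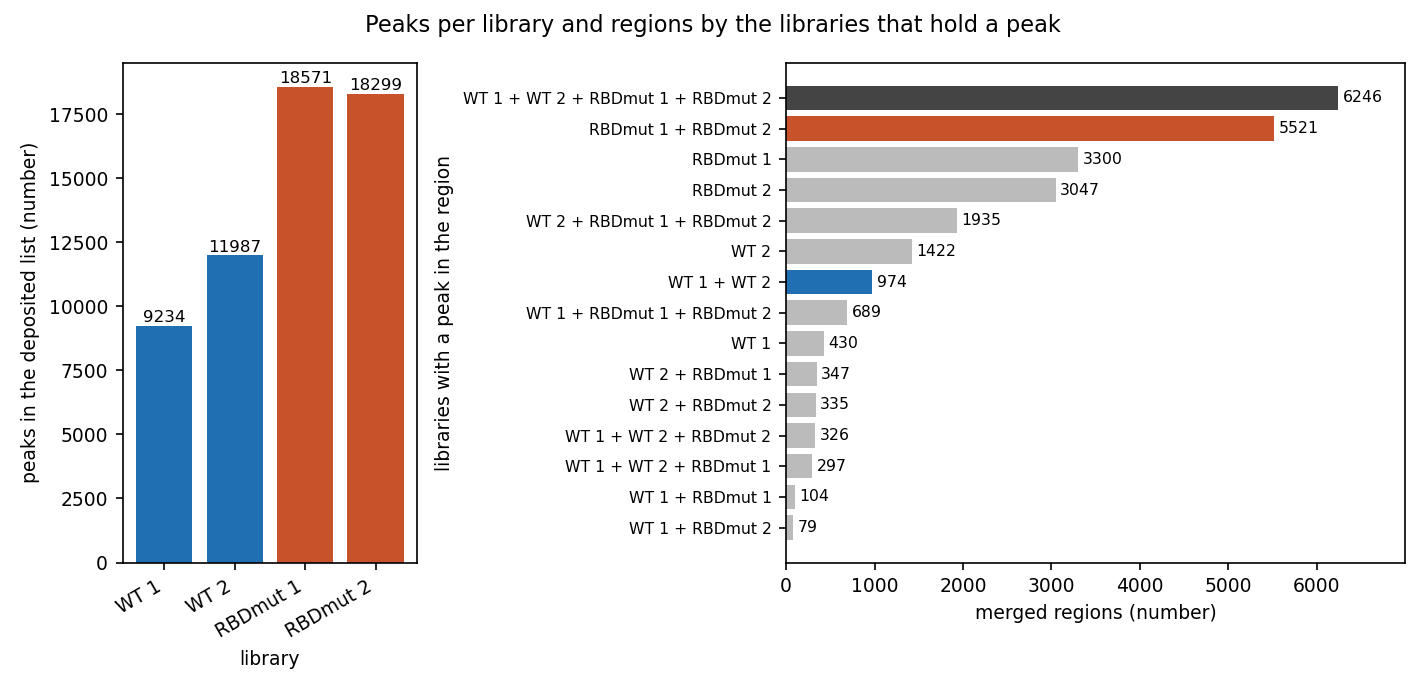
The left panel plots the number of peaks in each deposited list, WT in blue and RBDmut in orange. The right panel plots the number of merged regions by the set of libraries with a peak in them, with 6246 shared (dark), 5521 RBDmut-only (orange) and 974 WT-only (blue) regions, and all other sets in grey.

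Shared regions held the stronger peaks of every list, and group-only regions ranked lower. On a scale where 100 is the strongest peak of a list by q-value, the median percentile of peaks in shared regions was 62.0 and 70.2 in the WT lists and 79.5 and 79.6 in the RBDmut lists. RBDmut-only peaks had medians of 42.8 and 41.9, and WT-only peaks had medians of 38.7 and 49.1. Median fold enrichment in RBDmut replicate 1 was 9.10 in shared and 5.34 in RBDmut-only regions, and in WT replicate 1 it was 6.59 in shared and 5.50 in WT-only regions. Some ranked higher: 1418 RBDmut-only regions (25.7%) and 263 WT-only regions (27.0%) ranked in the top 50% of both lists of their group. In the top 10% of both lists were 18 RBDmut-only and 9 WT-only regions.

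The rank of a peak went with its presence in the other group. In the strongest decile of each list, between 98.1 and 98.9% of peaks overlapped a peak in at least 1 list of the other group. In the weakest decile this share was 71.4 and 61.2% for the WT lists and 19.7 and 20.3% for the RBDmut lists. For the other list of the same group it was 59.0 and 21.9% in WT and 40.9 and 40.4% in RBDmut. That is overlap with 1 list. For 1 list of the other group at a time, the mean share was 63.5 and 52.2% in WT and 14.1 and 14.4% in RBDmut.

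**Figure D2:**
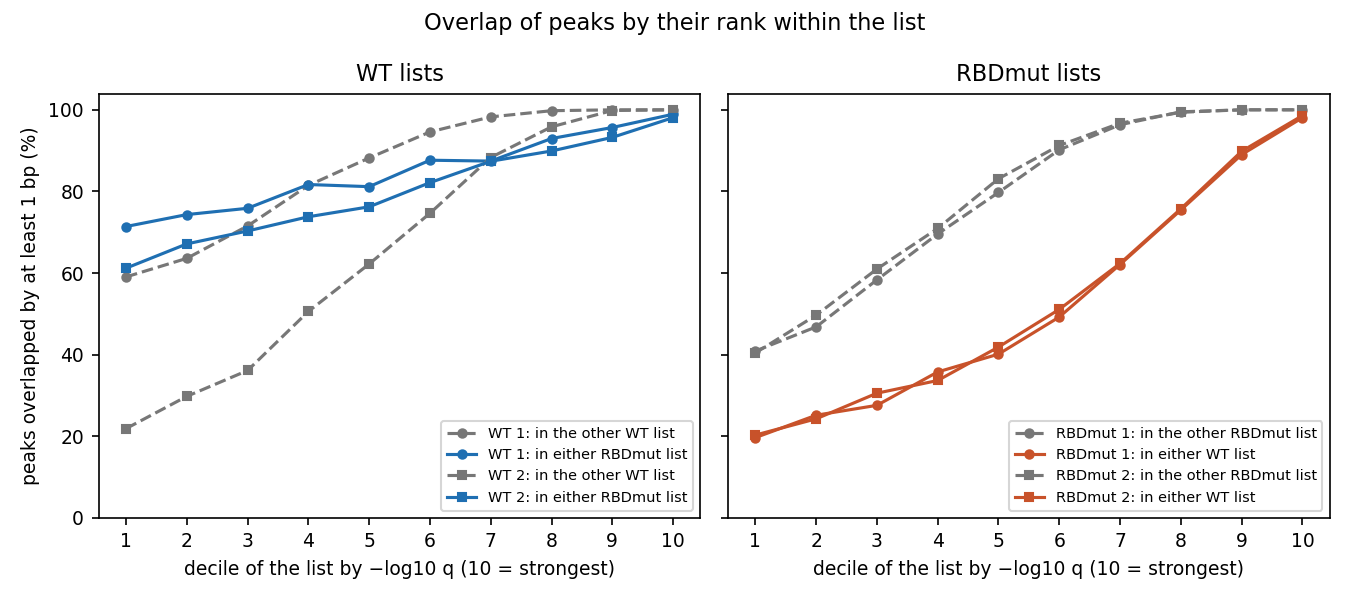
Share of peaks (%) overlapped by at least 1 bp, for each decile of a list ranked by −log10 q, with 10 the strongest decile: solid coloured lines are overlap with either list of the other group and dashed grey lines overlap with the other list of the same group, with 1 line per library. In the weakest decile the overlap with the other group was 71.4 and 61.2% for WT and 19.7 and 20.3% for RBDmut.

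Where both forms had a peak, the summits lay at nearly the same base. In 6026 shared regions with exactly 1 peak per list, the median distance between summits was 25 bp for the WT pair, 22 bp for the RBDmut pair and 24 to 26 bp for pairs of different forms. Summits lay within 50 bp of each other in 77.6% of these regions for the WT pair (Wilson 95% interval 76.5 to 78.6%), in 82.8% for the RBDmut pair and in 77.4 to 79.1% for pairs of different forms.

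The 10 shared regions with the best mean rank spread over 8 chromosomes. First was chromosome 12 from 116827672 to 116829117, where the fold enrichment was 37.4 and 45.4 in the WT lists and 60.0 and 67.0 in the RBDmut lists. Next came chromosome 10 from 117423686 to 117424903, with 63.0 and 48.9 in WT and 58.1 and 40.2 in RBDmut. The region on chromosome 11 from 1817379 to 1818312 had 58.0 and 75.1 in WT and 78.6 and 65.2 in RBDmut. The others were on chromosome 12 from 89858329 to 89859384 and from 75264840 to 75266403, chromosome 2 from 11672202 to 11673196, chromosome 9 from 95750292 to 95751389 and chromosome 4 from 143535831 to 143537119. Also among the 10 were chromosome 15 from 71388818 to 71389667 and chromosome X from 16680225 to 16681146.

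The best-ranked RBDmut-only region was on chromosome 5 from 128690518 to 128691292, with fold enrichments of 23.5 and 22.4 in the RBDmut lists and no peak in either WT list. It ranked at percentiles 96.9 and 97.0. The region on chromosome 4 from 65819931 to 65820727 had fold enrichments of 19.3 and 23.9, and that on chromosome 9 from 107707106 to 107707558 had 19.0 and 16.9. Among the next 7 were chromosome 5 from 98526292 to 98527018, chromosome 10 from 117192773 to 117193241, chromosome 2 from 237805107 to 237805722 and chromosome 13 from 58382665 to 58383258. The rest were chromosome 2 from 195429237 to 195429994, chromosome 12 from 81778602 to 81779066 and chromosome 6 from 68001823 to 68002786. A region without a listed peak can still hold signal below the peak caller's threshold.

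The best-ranked WT-only region was on chromosome 1 from 145259148 to 145259832, with fold enrichments of 10.3 and 10.0 in the WT lists. It ranked at percentiles 97.2 and 97.6 by q-value, and a higher rank at a lower fold goes with a higher local background. The regions ranked next had higher fold enrichment. On chromosome 11 from 70449755 to 70450292 it was 27.0 and 18.2 and on chromosome 17 from 27405485 to 27405961 it was 20.3 and 18.1. The other 7 lay on chromosome 3 from 134046366 to 134046881, chromosome 10 from 132924996 to 132925482 and from 28545684 to 28546191, chromosome 2 from 68076518 to 68077056, chromosome X from 3388242 to 3388661, chromosome 14 from 98596113 to 98596482 and chromosome 16 from 10684177 to 10684683.

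The last comparison was of how peaks were spread over the chromosomes. Chromosomes 4 and 6 took a higher share of the RBDmut lists, at 5.72 ± 0.136% against 4.77 ± 0.311% in WT for chromosome 4 and 6.57 ± 0.0226% against 5.74 ± 0.113% for chromosome 6 (SD, n = 2). Chromosome 22 took 1.01 ± 0.0316% of the RBDmut lists and 1.28 ± 0.0785% of the WT lists, and chromosome 11 took 4.05 ± 0.0115% and 4.52 ± 0.00989% (SD, n = 2). On 17 of 23 chromosomes (Y left out) the groups did not overlap, 7 with a higher and 10 with a lower share in RBDmut, where chance gives 33.3% of chromosomes.

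Against shared regions, RBDmut-only regions lay more often on chromosome 4 (6.52% and 4.92%, odds ratio 1.35, adjusted p = 0.00229) and chromosome 6 (7.43% and 5.65%, odds ratio 1.34, adjusted p = 0.00229), by Fisher's exact test. They lay less often on chromosome 16 (2.64% and 3.63%, odds ratio 0.720, adjusted p = 0.0170, Fisher's exact test). The tests were two-sided with Benjamini-Hochberg adjustment over 23 chromosomes, and took regions, not libraries, as units. WT-only regions lay more often on chromosome X (43 of 974, or 4.41%, against 2.42% of shared regions, odds ratio 1.86, adjusted p = 0.0196) and less often on chromosome 21 (6 of 974, adjusted p = 0.0483, Fisher's exact test). With lists of equal length, 6 chromosomes passed the threshold for each class, in place of 3 and 2. For WT-only regions chromosome 21 was among them and chromosome X was not.

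Part of the WT-only excess on chromosome X came from a regularly spaced cluster, which was chosen after its values were seen. Between 114959796 and 115004267, a span of 44.5 kb, the WT lists held 17 regions, 10 of them in both WT lists, and the RBDmut lists held none. The summits followed each other at a median spacing of 2954 bp, and 14 of 16 spacings were between 2.5 and 3.5 kb. The peaks were weak, with a median fold enrichment of 4.29 over 12 peaks in WT replicate 1 and 3.52 over 15 peaks in WT replicate 2. The cluster lay at high local background, with medians 1.65 and 1.84 times those of shared regions on chromosome X in the same lists. Without this cluster, 33 of 964 WT-only regions were on chromosome X (odds ratio 1.43, adjusted p = 0.449 by Fisher's exact test), and the call on chromosome 21 was lost as well (adjusted p = 0.0957).

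**Figure D3:**
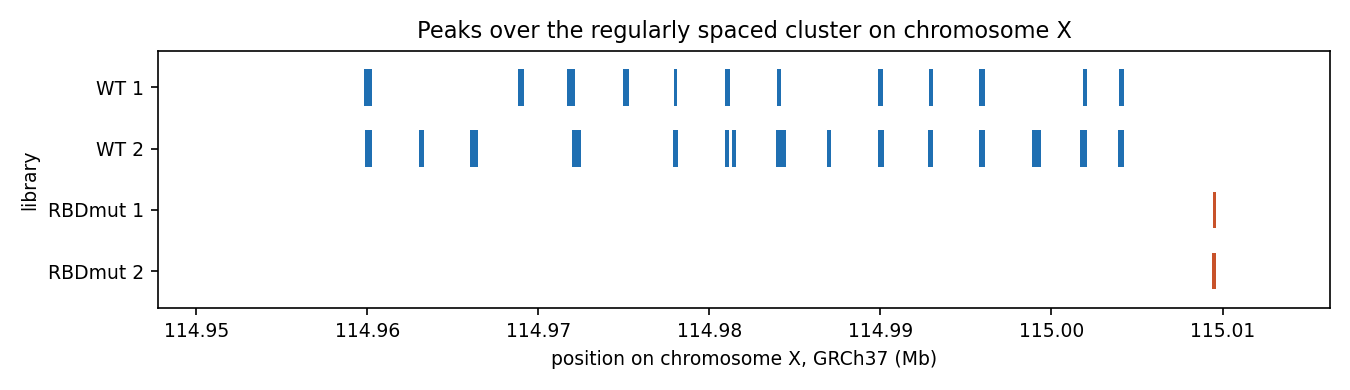
Map of chromosome X around the cluster (position in Mb, GRCh37), with each peak of the 4 lists drawn to scale as a box in the row of its library. Between 114959796 and 115004267 there were 12 and 15 peaks in the WT lists and 0 in each RBDmut list.

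The local background that the peak caller took from each input library differed between chromosomes and between groups. Relative to the median over shared regions of the same list, chromosome 20 stood at 2.00 and 2.06 in the WT libraries and 1.89 and 1.80 in the RBDmut libraries. MCF7 cells are known to carry extra copies of parts of this chromosome. Chromosome 6 stood at 0.800 and 0.849 in WT and 1.00 in each RBDmut library, and chromosome X at 0.677 and 0.758 in WT and 0.588 and 0.600 in RBDmut. Across 23 chromosomes, the log2 ratio of this background (RBDmut over WT) went with the log2 ratio of the share of peaks. Pearson's r was 0.648 (permutation p = 0.0009, adjusted p = 0.0018) and Spearman's rho was 0.622 (permutation p = 0.00188, adjusted p = 0.00188), both two-sided and adjusted over these 2 tests. Without chromosomes X and 22, the farthest from the median background ratio, r was 0.529. Chromosomes are not independent replicates, and the correlation describes these 4 libraries.

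**Figure D4:**
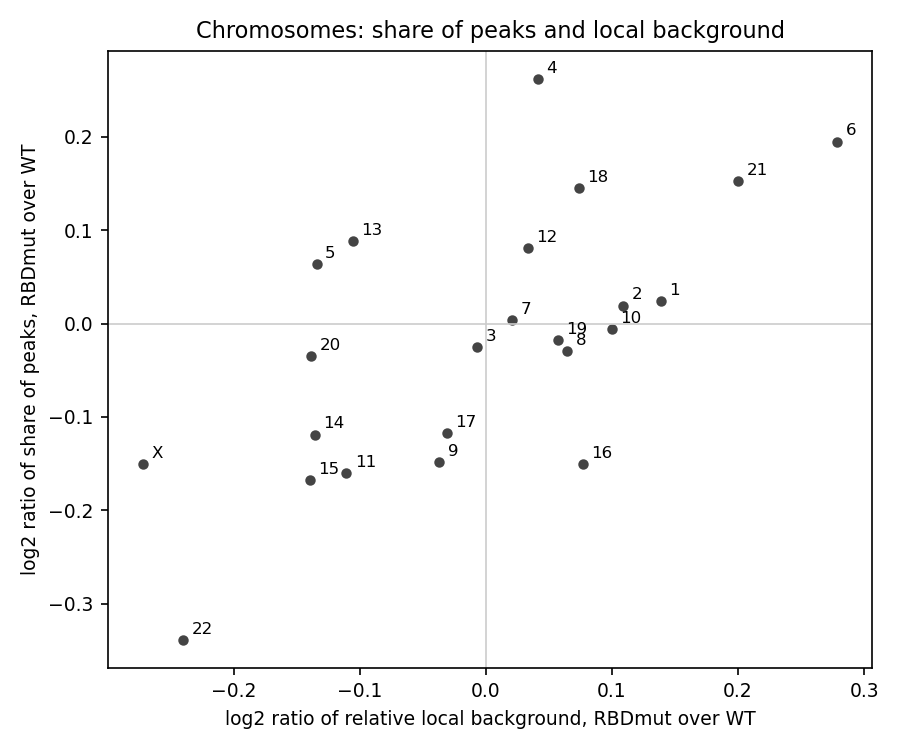
Each point is 1 of 23 chromosomes, with the log2 ratio (RBDmut over WT group means) of relative local background on the x axis and of the share of peaks on the y axis. Pearson's r was 0.648, with chromosomes 6 and 21 at the upper right and chromosomes X and 22 at the lower left.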

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

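The Jaccard index, the removal of peaks with fold under 3 and the restriction to regions in the top 50% of both lists were chosen after seeing the data. Of 56 alternative values, 38 stayed within the replicate spread or, for counts, within 1.5 times the reported count, and 18 did not. No alternative turned the direction of the difference in peak number or of the difference in overlap. With peaks of at least 10-fold enrichment the ratio of peak numbers, RBDmut over WT, was 2.09 in place of 1.74. Leaving out each library gave ratios of 1.54 to 2.00. The difference in overlap between pairs of the same and of different forms was 24.3 percentage points for peaks with −log10 q of at least 10 and 21.4 points by the Jaccard index in percent, against 20.6. In lists of equal length it was 29.0 points for the top 1000 peaks, 24.7 for the top 3000 and 15.3 with ranking by fold, against 17.6.

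At −log10 q of at least 10 there were 3762 shared and 3672 RBDmut-only regions; fewer peaks entered. Lists of equal length gave 1750 RBDmut-only and 1812 WT-only regions, since shortening removes most from the longer RBDmut lists. Such regions could have a peak below the cut in the other group. Leaving out each library gave 6213 to 8874 RBDmut-only and 1273 to 2403 WT-only regions, as fewer lists then had to hold or lack a peak. The top 50% of both lists held 1418 RBDmut-only and 263 WT-only regions by construction. Without peaks of fold under 3 there were 5370 and 925. Ranked by fold, the gap in median percentile to shared peaks was −35.2 for RBDmut-only and −15.4 for WT-only peaks, against −37.2 and −22.3; the cause was not tested. Lists of equal length gave 6 chromosomes past the threshold for RBDmut-only and 6 for WT-only regions, against 3 and 2; the cause was not tested.

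Both groups use replicate numbers 1 and 2, but pairs of the same number overlapped no more than pairs of different numbers (56.0% and 56.0%). With the replicate number as a block the ratio of peak numbers was 1.75, from 2.01 and 1.53 within number 1 and number 2 (exact sign-flip permutation p = 0.5, the smallest it can give). Alternatives for promoter windows, motif windows and mismatches and gene-list windows were not run, nor were equal-length lists or leaving out libraries for those results, because the gene table is on another build. The weak end of each list was the least repeatable: in the lowest decile 59.0 and 21.9% of WT peaks and 40.9 and 40.4% of RBDmut peaks were in the other list of their group. How far depth sets this was not tested.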

Other observations

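The tests of library depth, of group-only peaks at the weak end of their lists and of the share of peaks with high local background were chosen only after the result was seen, and the bins, peak clusters and neighbouring regions described here were looked at after the lists had been compared.

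RBDmut-only regions gathered in some stretches of the genome with few shared regions. In bins of 5 Mb, 12 of 549 differed from shared regions past an adjusted p of 0.05 (Fisher's exact test, two-sided, Benjamini-Hochberg), 8 with more and the others with fewer RBDmut-only regions. Chromosome 4 from 30000001 to 35000000 held 18 RBDmut-only regions and 1 shared region (odds ratio 20.4, adjusted p = 0.00521, exact test). Chromosome 13 from 65000001 to 70000000 held 27 and 5 (odds ratio 6.13, adjusted p = 0.00521, exact test). In the opposite direction, chromosome 16 from 85000001 to 90000000 held 13 RBDmut-only and 46 shared regions (odds ratio 0.318, adjusted p = 0.0129), and chromosome 22 from 25000001 to 30000000 held 0 and 14 (adjusted p = 0.0129, exact tests). Among the 8 bins with more were chromosome 1 from 190000001 to 195000000 and chromosome 6 from 100000001 to 105000000. These lay in bins of 10 Mb with a higher local background in RBDmut (log2 ratios over WT of 0.552 and 0.502, the highest of 270 bins being 0.731). The others of the 8 were not in the bins with the highest ratios. For WT-only regions 1 of 491 bins passed, chromosome X from 110000001 to 115000000 with 8 WT-only and 0 shared regions (adjusted p = 5.25e-05, exact test), which holds most of the regularly spaced cluster.

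Regions of all classes lay near shared ones more often than after a shift by 1 Mb. A shared region lay within 10 kb of 14.4% of RBDmut-only and 16.1% of WT-only regions, against 4.49% and 5.03% after the shift. For regions in 1 RBDmut list or 1 WT list only the shares were 13.8% and 16.6%, against 4.35% and 3.78%. None of 3 Fisher's exact tests of RBDmut-only against WT-only regions, and of each against regions in 1 list of its group, passed (adjusted p = 0.507, 0.553 and 0.749). A scan for at least 8 regions with gaps of at most 5 kb found only the chromosome X cluster in the WT lists. In the RBDmut lists it found chromosome 1 from 155090115 to 155102681 (8 regions, 2 also in WT), chromosome 11 from 118781052 to 118793447 (9 regions, 5 also in WT) and chromosome 21 from 16572171 to 16584238 (8 regions, 6 also in WT).

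The RBDmut lists were longer. The tables argue against deeper RBDmut libraries, since their mean number of filtered ChIP tags was 0.977 times that of WT. At equal list length the WT pair overlapped by 15.1 percentage points more than the closest pair of different forms. This argues against a uniform difference in enrichment strength as the only difference, since stronger lists would then have held the WT peaks at least as well. The cut compares peaks by rank, so it cannot decide whether stronger enrichment at the same places made the lists longer. In full lists, 74.4 and 74.5% of WT replicate 2 peaks overlapped the RBDmut lists, against 65.9% for WT replicate 1. WT replicate 1 went the other way, with 80.3% for each RBDmut list against 85.7% for WT replicate 2. A change in binding with the mutation stays open as a hypothesis, as does a batch of library preparation, which cannot be told apart from the ERα form. Enrichment strength could still add to the number of peaks.

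Several explanations were weighed for regions replicated in 1 group and absent from the other. Focal copy number changes were predicted to put over 50% of a class in its 10 fullest bins of 5 Mb. Those bins held 8.01% of WT-only and 5.09% of RBDmut-only regions, against 6.63% of shared regions in theirs. This argues against a few focal changes as the main source of either class. Focal changes scattered over many bins would not show in this measure, so they stay open. High input was tested by the median local background of group-only peaks. It was at most 0.800 times that of shared peaks for WT-only and 0.937 times for RBDmut-only peaks, under the bound set beforehand. At most 11.5% of WT-only and 13.5% of RBDmut-only peaks exceeded 1.5 times the shared median. Weaker peaks pass the threshold more readily at low background, and group-only peaks were weaker than shared ones, so this comparison cannot decide. Peaks in neither shared nor group-only regions, also weak, exceeded it less often in every list (9.86 and 9.32% in WT, 12.3 and 10.9% in RBDmut). High input stays open, and the chromosome X cluster lay at high local background. Peaks too weak to pass the threshold in the other group stay open for both classes: the lower median percentile was 38.7 for WT-only and 41.9 for RBDmut-only peaks, but being in both lists of a group already removes weak peaks, and overlap with the other group rose with rank. Broad copy number gains were predicted to leave under 20% of a class in bins where the background was not higher in its own group. Over 40% was to speak against them. The share was 53.2% for WT-only regions, above both bounds. For RBDmut-only regions it was 32.9%, between the bounds of 20 and 40% set beforehand. Shared regions already stood at 60.3% by the WT measure and 39.7% by the RBDmut measure, so the bounds cannot decide. Broad gains and a change in binding cannot be told apart for either class. Both classes lay in bins with a higher background in their own group more often than shared regions did. For RBDmut-only regions it was 67.1% against 60.3% (odds ratio 1.34, p = 4.98e-14, Fisher's exact test). For WT-only regions it was 46.8% against 39.7% (odds ratio 1.33, p = 5.06e-05, Fisher's exact test). These p-values were not adjusted and took regions as units. All regions of a bin share 1 value and are not independent, so the p-values overstate the evidence.

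Shares of peaks shifted between chromosomes, and copy number differences between the cell populations may account for part of this. The correlation of share with local background across chromosomes, predicted to exceed 0.5 if so, was 0.648. In 270 bins of 10 Mb, the log2 ratio of background between the groups had an SD of 0.206, against 0.106 and 0.102 for the other splits of the libraries, and reached 0.73 on chromosome 6 from 60000001 to 70000000, 0.73 on chromosome 16 from 1 to 10000000 and −0.61 on chromosome X from 10000001 to 20000000. Chromosome 5 ran the other way, with a higher share in RBDmut and a background of 0.907 ± 0.0136 in WT and 0.826 ± 0.0367 in RBDmut (SD, n = 2). So did chromosomes 8, 13 and 16, with log2 ratios of background of 0.064, −0.106 and 0.077. Their shares differed by −0.108, 0.160 and −0.368 percentage points, RBDmut minus WT. The background of chromosome 13 overlapped between the groups, and the difference on chromosome 16 was within the spread between WT libraries. Chromosome 4 shifted in share with a small log2 ratio of background (0.041) and overlapping groups. Chromosomes 3, 12 and 18 also had small log2 ratios of background (−0.007, 0.033 and 0.074) with overlapping groups. The other chromosomes with non-overlapping shares shifted in the direction of their background. A change in binding stays open for chromosomes 3, 4, 5, 8, 12, 13, 16 and 18. For the others it cannot be told apart from copy number. Background here was read at the peaks, and whole input libraries would be needed to measure copy number.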
